A study of Mus musculus with 8 samples.

How the data were processed

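The data are 8 arrays of total RNA from flow-sorted CD45-positive, CD11b-positive, Ly6C-high cells, 4 from sham-treated and 4 from irradiated mice. Per the labels' protocols, 25 ng of RNA per sample was amplified by ribo-SPIA, an isothermal linear amplification, and the fragmented product was labelled with biotin. The deposited values are on a log2 scale, as read from their range; the authors made them with RMA and Partek, named without versions or parameters, per the submitters' processing notes. The steps and settings of that normalization are not given in the sources used here. Each mouse gave 1 array, groups were taken from the sample titles, and the number of arrays limits the precision. The gene-wise p-values measure a difference against the spread among the 4 mice of each group. Those of the list test camera, described below, compare a list's genes with all other genes and do not measure that spread. No array scan dates or batches were used, since none are given in the sources used here.

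The value table holds 34365 probe set rows. A table of the platform's annotation gave 1 gene symbol for 23521 rows, several for 1814 and none for 9030, which are unnamed here. Rows with 1 symbol were kept, and for the 1082 symbols with more than 1 row the row with the highest mean over the 8 arrays was taken, which left 22180 genes. The Entrez identifiers of 21994 of them were found in the RefSeq table of mouse assembly GRCm38.p6, which was used for names only. No filter on dim genes was applied: 9868 genes had a mean under 4.70, the median of all rows, and no detection calls were used.

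The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are irradiated minus sham on the log2 scale, with standard errors and 95% intervals from the moderated fit; SDs are those of the 4 mice. Across all genes the median difference was -0.03. A total of 33 gene lists, of pathways, of the sorted cell type and of other cell types, was fixed in advance; 889 of their 985 distinct symbols were measured. Each list was tested two-sided with limma's camera at its preset correlation of 0.01, which compares a list with all other genes, adjusted over the 33 lists. Beside it were run camera with the correlation estimated from each list and fry, which asks whether a list's own genes move on balance one way; a two-sided exact permutation of each list's mean over the 70 assignments of the arrays was added after the data were seen. Counts of list members are given adjusted over all genes and adjusted over the list alone. With an estimated correlation 0 lists passed, and by fry 0 passed, against 15 with the preset correlation. Fry for change in either direction passed 2, p53 targets and cholesterol and fatty acid synthesis, each at an adjusted p of 0.0407. Estimated correlations ran from 0.03 for erythroid and platelet markers to 0.68 for type I interferon genes, all above the preset 0.01. The estimate for p53 targets was 0.20. Camera's calls at the preset value thus rest on a lower correlation than the data gave.

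Genes named in the text follow a rule. It took the 12 genes per direction with the smallest p, since none passed the threshold, leaving out predicted genes, small RNAs, receptor families and antigen receptor segments. It added the 2 members of each list with the smallest p, of which the text gives some, and Ptprc, Itgam, Ly6c2, Ly6c1, Ccl2, Ccr2, Cdkn1a and Mdm2 whatever their result. Genes named outside the rule are said to be so. Apart from the exact permutation of list means, the checks of the closing section and the alternatives named as added, the tests, lists, rule and alternatives were fixed before the data were examined.

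The gene-wise test was tested on simulated data drawn with each gene's mean and a spread drawn from its fitted variance. The list test was tested on data in which 1 list was raised by 0.4, which it called at an adjusted p of 7.03e-30 with 0 other lists called; its simulated genes varied independently of one another, so it does not test how the preset correlation holds for lists whose genes vary together. Alternatives were quantile normalization, subtraction of array medians, removal of dim genes, the mean of a gene's rows, a trended and robust variance, array weights, the mouse number as a block, all rows tested, a minimum change of 1.5-fold, and each array left out in turn. After seeing the data, 2 more were added: the T and NK cell list mean as a covariate, and sham mice 2 and 3 left out together. Principal components were taken from the 2000 most variable genes, and plots were drawn with matplotlib 3.10.9.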

Results

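Transcript levels were measured on 8 Affymetrix arrays, each hybridised with RNA from the Ly6C-high myeloid cells of 1 mouse. The cells were sorted by flow cytometry as CD45-positive, CD11b-positive and Ly6C-high, the surface profile of inflammatory monocytes and the macrophages that arise from them. They came from subcutaneous tumours grown for 14 days in female C57BL/6 mice from a cell line of a spontaneous mouse pancreatic cancer. The tumours of 4 mice had received 20 Gy, an ablative dose, and those of 4 mice a sham treatment, and both groups were harvested 1 day later. The array medians lay between 4.68 and 4.73 on the log2 scale, and the arrays correlated at 0.976 to 0.988 with one another. Of the sort's own markers, Ptprc, which encodes CD45, stood at 11.66 ± 0.05 in sham mice and 11.62 ± 0.09 in irradiated mice (SD, n = 4 each). Itgam, which encodes CD11b, stood at 10.94 ± 0.18 and 11.12 ± 0.12. Ly6c2, which encodes the Ly6C antigen, stood at 11.55 ± 0.42 and 11.76 ± 0.71, and its difference of 0.21 (95% interval -0.52 to 0.94) ranged from -0.02 without irradiated mouse 1 to 0.54 without irradiated mouse 3, with 0.03 without sham mouse 4 and 0.35 without sham mouse 2. Ly6c1 lay near the floor of the arrays at 2.61 ± 0.16 and 2.88 ± 0.23.

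The comparison asked which genes of tumour monocytes and macrophages are associated with irradiation of the tumour 1 day earlier. Targets of the DNA damage regulator p53 rose as a group after 20 Gy: their mean level was 7.12 ± 0.05 in sham mice and 7.45 ± 0.22 in irradiated mice (SD, n = 4 each), and each of the 4 irradiated mice lay above each of the 4 sham mice. Genes of the type I interferon response also rose as a group, by 0.52 ± 0.28 (SE) on the log2 scale, with the highest levels in irradiated mice 1 and 2. Irradiated mice 3 and 4 lay within the range of the sham mice. Genes of DNA replication and genes of cholesterol and fatty acid synthesis fell as groups, by 0.19 and 0.18 on the log2 scale. Each irradiated mouse lay below each sham mouse for cholesterol and fatty acid synthesis but not for DNA replication. Markers of T and NK cells, B cells and neutrophils were lower on average in the irradiated group and varied widely within both groups. These group calls came from limma's camera test with its preset correlation between genes, and the adjusted p was 0.622 or more for every list with an estimated correlation.

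No single gene of the 22180 tested passed the adjusted threshold in limma; the smallest adjusted p was 0.545. At an unadjusted p under 0.05 there were 1347 genes, 454 higher and 893 lower in irradiated mice, where chance alone gives 1109. The 2 groups did not overlap for 816 genes, 3.68% of those tested, against 2.86% by chance. The median 95% interval reached 0.30 on the log2 scale to either side. In simulated data with the same spread per gene, 200 genes among 22180 were changed. Of those changed by 1 on the log2 scale 78% were recovered, and of those changed by 1.5 98%, with 6 false calls. With 20 changed genes, 35% of those changed by 1 were recovered, with 0 false calls. The simulated genes varied independently of one another, unlike those of the real arrays, so these shares may not hold here. Without irradiated mouse 1, 1 gene passed, the histone gene H2ac15, which was lower after irradiation and belongs to a family of near-identical copies that array probes may not separate.

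The genes with the smallest p on the higher side included several that p53 is known to induce. Psrc1, a microtubule-associated p53 target, differed by 0.98 ± 0.15 (SE), and Phlda3, a repressor of Akt signalling, by 1.07 ± 0.20. Trp53inp1, a stress-induced cofactor of p53, stood at 6.53 ± 0.14 in sham and 7.80 ± 0.51 in irradiated mice (SD, n = 4 each), a 2.41-fold difference. Ccng1, which encodes cyclin G1, stood at 10.03 ± 0.13 and 11.14 ± 0.49, a 2.16-fold difference. Tnfsf4, which encodes the T cell costimulator OX40 ligand, stood at 4.67 ± 0.48 in sham and 6.68 ± 0.87 in irradiated mice. Ddias, a DNA damage-induced apoptosis suppressor, differed by 1.13 ± 0.21, the receptor tyrosine kinase gene Epha2 by 1.00 ± 0.17, the glutamate receptor gene Gria3 by 1.08 ± 0.20 and the exocyst gene Exoc4 by 0.96 ± 0.19. Differences of 0.44 to 0.64 were seen for St14, a membrane protease gene, Zfyve21 and the cation channel gene Trpm2. On the lower side, H2ac15 and Adam4 each differed by -1.18, Clec2g by -0.91 and Zfp825 by -0.75. The fatty acid elongase gene Elovl6 differed by -0.81, and the fumarate hydratase gene Fh1, an enzyme of the citric acid cycle, by -0.49 ± 0.09. The remaining 6 genes were Ankmy2, Ankrd49, Lpcat4, Kynu, Arl2bp and Zfp672, with differences from -0.69 to -0.47. The mean of 1 or both groups lay under 4.70, the median of all probe sets, for Tnfsf4, Ddias, Adam4 and Clec2g, so the size of their differences is uncertain. Signal over background was not tested. In all 24 genes the groups of 4 did not overlap, and their adjusted p ranged from 0.545 to 0.819 in limma.

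Of the 36 measured p53 targets, 29 were higher in irradiated mice, 13 of them at an unadjusted p under 0.05 and 8 with p adjusted over the list alone, against 0 adjusted over all genes. The list rose by 0.33 ± 0.11 (SE) on average, with a median of 0.26 (camera adjusted p = 1.39e-12; adjusted p = 0.622 with an estimated correlation). Besides Psrc1, Trp53inp1, Phlda3 and Ccng1, the list-wise adjustment passed Mdm2, which encodes the ubiquitin ligase that limits p53, at 8.91 ± 0.11 in sham and 9.56 ± 0.46 in irradiated mice (SD, n = 4 each). The other 3, named after their values were seen, were the death receptor gene Tnfrsf10b (0.76 ± 0.20, SE), the exonuclease gene Aen (0.61 ± 0.15) and the translesion polymerase gene Polk (0.66 ± 0.18). Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 11.66 ± 0.23 in sham and 12.05 ± 0.18 in irradiated mice and did not pass within the list. The list means of the sham mice lay between 7.06 and 7.19, and those of the irradiated mice between 7.25 and 7.74, highest in mouse 3. A two-sided exact permutation of the 8 list means gave p = 0.0286, the smallest the 70 assignments allow. After adjustment over the 33 lists the exact p was 0.471. Only 2 lists reached that smallest p, so no list could pass after this adjustment. Fry for change in either direction gave the p53 list an adjusted p of 0.0407.

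**Figure D1:**
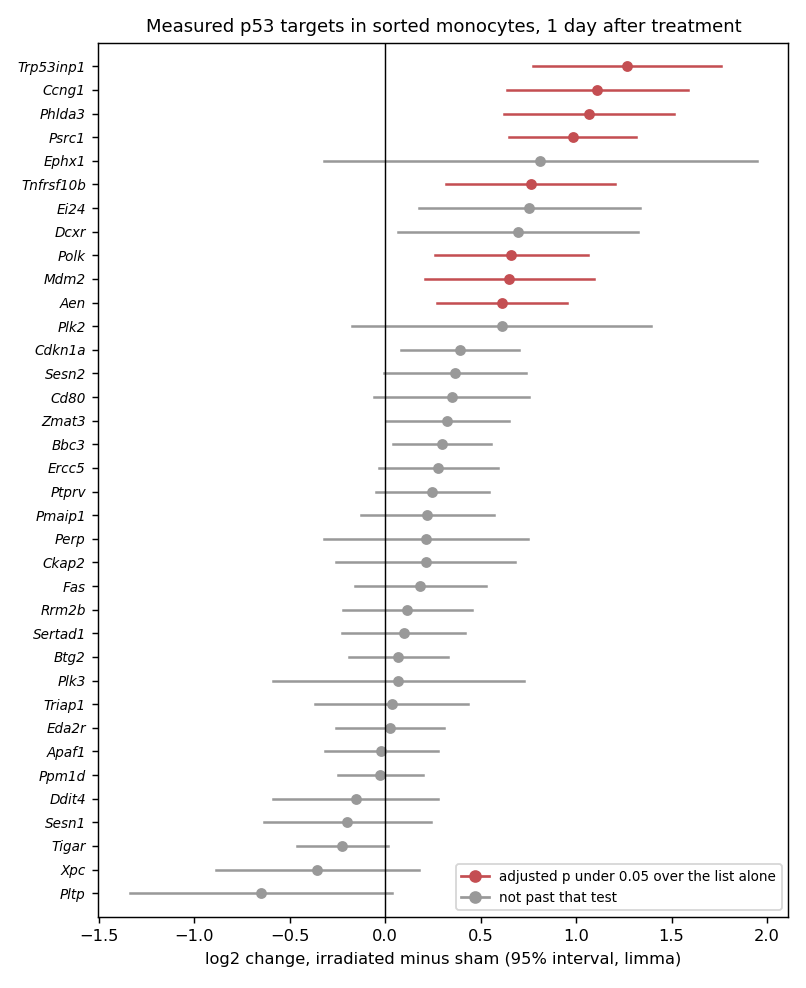
Log2 change of each measured p53 target, irradiated minus sham (x axis, 4 mice per group), with its 95% interval from limma. Of 36 genes, 29 lie above 0 and the 8 in red passed after adjustment over the list alone.

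Of the 35 measured genes of the type I interferon response, which cells switch on to restrict viruses, 34 were higher in irradiated mice and 7 of them at an unadjusted p under 0.05; 0 passed adjusted over the list alone or over all genes. The list rose by 0.52 ± 0.28 (SE), with a median of 0.51 (camera adjusted p = 8.11e-19; adjusted p = 0.622 with an estimated correlation). The list means of irradiated mice 1 and 2 were 9.42 and 9.06, those of irradiated mice 3 and 4 were 8.31 and 8.38, and those of sham mice lay between 8.06 and 8.46. The difference between the groups was 0.31 without irradiated mouse 1, and a two-sided exact permutation of all 8 list means gave p = 0.171. The transcript of Mx1, a member of this list, stood at 9.02 and 8.56 in irradiated mice 1 and 2. It stood at 7.14 and 6.92 in irradiated mice 3 and 4, and at 6.59 ± 0.28 in sham mice (SD, n = 4). Ifi204, a DNA sensor of the interferon-inducible family, differed by 0.43 ± 0.13 (SE) with no overlap of the groups. The list of interferon gamma response genes rose by 0.17 ± 0.10 (SE), with 15 of 20 measured genes higher (camera adjusted p = 0.00182; adjusted p = 0.622 with an estimated correlation). Its difference was 0.09 and the adjusted p 0.118 without sham mouse 1. The chemokine gene Cxcl10, one of its members, stood at 10.19 ± 0.18 in sham and 10.85 ± 0.62 in irradiated mice, and the guanylate-binding protein gene Gbp5 differed by 0.33 ± 0.17 (SE). Without irradiated mouse 1 their differences were 0.43 and 0.20.

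**Figure D2:**
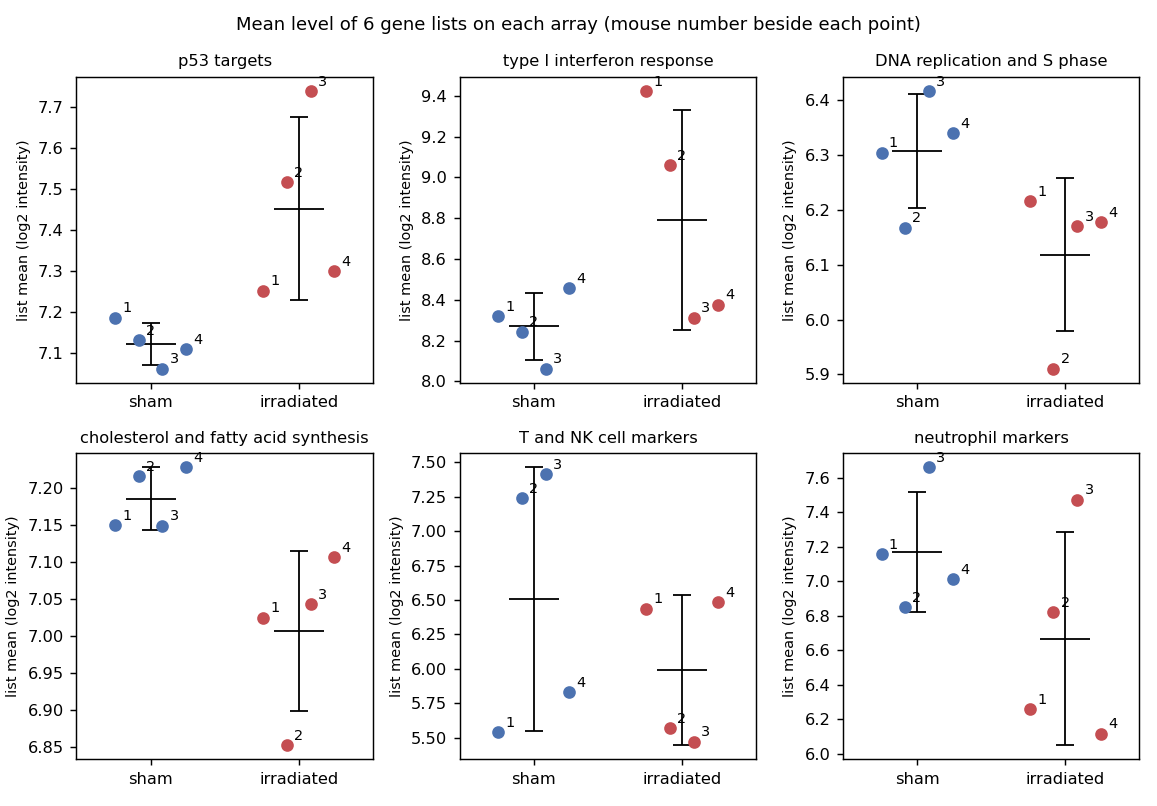
Mean log2 level of 6 gene lists on each of the 8 arrays (y axis), with sham mice in blue, irradiated mice in red and the mouse number beside each point; the bars show the group mean and SD (n = 4). The p53 list means of irradiated mice, 7.25 to 7.74, lie above those of sham mice, 7.06 to 7.19, while the T and NK cell list spans 5.47 to 7.41 over both groups.

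Genes of DNA replication and S phase fell by 0.19 on the log2 scale, with 27 of 32 measured genes lower (camera adjusted p = 0.00125; adjusted p = 0.622 with an estimated correlation). Ccne1, which encodes cyclin E1 of the G1/S transition, stood at 5.57 ± 0.13 in sham and 4.91 ± 0.27 in irradiated mice (SD, n = 4 each) and passed when adjusted over the list alone but not over all genes; the replication factor gene Mcm10 differed the other way, by 0.35 ± 0.10 (SE). Without irradiated mouse 2 the list's difference was -0.12 and its adjusted p 0.0509. A two-sided exact permutation of the list means gave p = 0.114. The groups overlapped, with sham mouse 2 at 6.17 below irradiated mouse 1 at 6.22. DNA repair genes fell by 0.11, with 21 of 32 lower (camera adjusted p = 0.046; adjusted p = 0.823 with an estimated correlation), among them the checkpoint kinase gene Atr (-0.43 ± 0.14, SE) and the Ku70 gene Xrcc6 (-0.37 ± 0.12); none passed adjusted over the list alone. Its call was lost without sham mouse 1 or 3 or irradiated mouse 1, 2 or 3, with adjusted p from 0.055 to 0.446, and its difference was -0.07 without sham mouse 3 and -0.16 without sham mouse 2. It was also lost with the T and NK list mean as a covariate, a setting chosen after seeing the data (adjusted p = 0.115). The G2/M and mitosis list, with 18 of 34 genes lower, had a median of -0.01 and did not pass (camera adjusted p = 0.894). It passed as higher in irradiated mice without sham mouse 3 (adjusted p = 0.0123) or irradiated mouse 2 (adjusted p = 0.00425).

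Genes of cholesterol and fatty acid synthesis fell by 0.18 on the log2 scale, from 7.19 ± 0.04 in sham to 7.01 ± 0.11 in irradiated mice (SD, n = 4 each), and each irradiated mouse lay below each sham mouse. Of 24 measured genes 19 were lower (camera adjusted p = 0.00398; adjusted p = 0.622 with an estimated correlation), and a two-sided exact permutation of the list means gave p = 0.0286, or 0.471 after adjustment over the lists. Elovl6 passed adjusted over the list alone but not over all genes, and Lss, the lanosterol synthase gene, differed by -0.36 ± 0.12 (SE). The camera call was lost without irradiated mouse 2 (adjusted p = 0.0729). Fry for change in either direction gave this list an adjusted p of 0.0407. Genes of oxidative phosphorylation, the mitochondrial respiratory chain, fell by 0.10 with 30 of 33 lower, among them Uqcrc2 (-0.17 ± 0.09, SE) and Ndufv2 (-0.28 ± 0.15, or -0.18 without irradiated mouse 2), and none passed adjusted over the list alone (camera adjusted p = 0.00977; adjusted p = 0.823 with an estimated correlation). This call was lost without sham mouse 2 (adjusted p = 0.215, difference -0.06) or irradiated mouse 2 or 4 (adjusted p = 0.0729 and 0.0725), or with the T and NK list mean as a covariate, a setting chosen after seeing the data (0.132).

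Several inflammatory and macrophage lists rose by 0.13 or less, with no gene past the threshold adjusted over all genes or over the list alone. Genes of macrophage maturation and efferocytosis, the clearance of dying cells, rose by 0.13 with 23 of 35 higher (camera adjusted p = 0.0111; adjusted p = 0.823 with an estimated correlation); the adhesion molecule gene Vcam1 differed by 0.80 ± 0.28 (SE) and the cholesterol exporter gene Abcg1 by 0.41 ± 0.13. Matrix remodelling and angiogenesis genes rose by 0.10 with 21 of 29 higher (camera adjusted p = 0.0123; adjusted p = 0.622 with an estimated correlation), and the gelatinase gene Mmp2 stood at 7.69 in irradiated mouse 3 against 5.71 to 5.80 in the other 3 irradiated mice. NF-kB and inflammatory cytokine genes rose by 0.08 with 22 of 34 higher (camera adjusted p = 0.0443; adjusted p = 0.823 with an estimated correlation), including the cytokine gene Il27 (0.43 ± 0.15, SE). Chemokine genes rose by 0.08 with 14 of 26 higher (camera adjusted p = 0.046; adjusted p = 0.823 with an estimated correlation). Ccl2, which encodes the main monocyte attractant, stood at 11.17 ± 0.52 in sham and 11.75 ± 0.17 in irradiated mice (SD, n = 4 each), a difference of 0.58 (95% interval 0.08 to 1.09) at an adjusted p of 0.819 in limma, or 0.36 without sham mouse 3. Ccr2, the gene of its receptor, stood at 11.57 ± 0.07 and 11.46 ± 0.17, a difference of -0.12 (95% interval -0.36 to 0.13), or -0.03 without irradiated mouse 3. The immediate early and dissociation stress list, which also responds to tissue handling, rose by 0.08 with 22 of 32 higher (camera adjusted p = 0.0108; adjusted p = 0.823 with an estimated correlation), led by Klf6 (0.28 ± 0.11, SE). Macrophage maturation genes were lower where T and NK cell markers were higher within both groups. Their list means lay between 8.79 and 9.19 in sham mice 2 and 3 and irradiated mice 1 and 4, the arrays with the highest T and NK markers. They lay between 9.24 and 9.59 in sham mice 1 and 4 and irradiated mice 2 and 3. With the T and NK list mean as a covariate, a setting chosen after seeing the data, none of these 5 lists passed. The adjusted p was then 0.725 for macrophage maturation, in the opposite direction, 0.749 for NF-kB, 0.752 for chemokines, 0.614 for immediate early genes and 0.0642 for matrix remodelling. Each of the 5 calls was also lost without at least 1 array. The adjusted p then reached 0.601 for macrophage maturation (lost without sham mouse 2 or 3 or irradiated mouse 2 or 3) and 0.0818 for matrix remodelling (sham 1 or 2). It reached 0.622 for NF-kB (every array but sham 4 and irradiated 1), 0.519 for chemokines (sham 1, 2 or 3 or irradiated 2 or 3) and 0.146 for immediate early genes (sham 2 or 3 or irradiated 2, 3 or 4). With each array left out in turn, the differences ranged from -0.01 (without sham 3) to 0.19 (sham 4) for NF-kB, from -0.04 (sham 3) to 0.22 (sham 4) for chemokines and from 0.02 (sham 3 or irradiated 3) to 0.26 (irradiated 4) for macrophage maturation. They ranged from 0.05 (irradiated 3) to 0.16 (sham 4) for matrix remodelling and from 0.03 (sham 2 or 3 or irradiated 3) to 0.17 (irradiated 1) for immediate early genes.

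Markers of other cell types that the gate could have carried were uneven between arrays. T and NK cell markers fell by 0.52 on the log2 scale, with 27 of 30 measured genes lower (camera adjusted p = 0.00182; adjusted p = 0.823 with an estimated correlation), but their list means were 5.54, 7.24, 7.41 and 5.83 in sham mice 1 to 4 and 6.44, 5.57, 5.47 and 6.48 in irradiated mice 1 to 4. Il7r, a lymphocyte cytokine receptor gene, differed by -0.87 ± 0.26 (SE) and the NK receptor gene Klrd1 by -0.81 ± 0.27. Il7r did not follow the list means. It stood at 9.19, 9.28, 9.42 and 9.45 in sham mice 1 to 4. In irradiated mice 1 to 4 it stood at 7.64, 8.95, 8.96 and 8.33. Neutrophil markers fell by 0.50 with 22 of 29 lower (camera adjusted p = 0.0494; adjusted p = 0.823 with an estimated correlation). Camp, a neutrophil granule gene, stood at 8.02 in sham mouse 2 and 10.1 in sham mouse 3 and between 3.08 and 3.69 on the other 6 arrays, and Prtn3 differed by -0.44 ± 0.15. B and plasma cell markers fell by 0.30 with 19 of 22 lower (camera adjusted p = 0.0302; adjusted p = 0.823 with an estimated correlation), including the B cell kinase gene Blk (-0.32 ± 0.11). No gene of these lists passed over all genes or adjusted over the list alone. The T and NK difference was -0.84 without sham mouse 1 and -0.34 without irradiated mouse 3. Its call was lost without sham mouse 2 (adjusted p = 0.215, difference -0.27), sham mouse 3 (0.446, -0.21) or irradiated mouse 2 (0.0528). With sham mice 2 and 3 both left out, a setting chosen after seeing the data, the list was higher in irradiated mice (adjusted p = 0.000346). The neutrophil call was lost without sham mouse 1 or 3 or irradiated mouse 1, 2 or 4 (adjusted p = 0.0729 to 0.631), with differences of -0.77 without irradiated mouse 3 and -0.32 without irradiated mouse 4. The B cell call was lost without sham mouse 2 or 3 or irradiated mouse 2 or 3 (adjusted p = 0.0776 to 0.584), with differences of -0.15 without sham mouse 3 and -0.20 without irradiated mouse 3. With the T and NK list mean as a covariate, also chosen after seeing the data, the B cell call was lost as well (adjusted p = 0.652).

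The other 17 lists did not pass camera. The Ly6C-high monocyte identity list had a median difference of 0.01 (adjusted p = 0.183), with 14 of 27 genes higher, and passed as higher without irradiated mouse 3 (adjusted p = 0.00173). Antigen presentation genes had medians of 0.00 for MHC class I (adjusted p = 0.541) and -0.08 for class II (0.427); the class II chaperone gene H2-Oa differed by -0.55 ± 0.21 (SE), or -0.36 without sham mouse 4. Chemokine and growth factor receptors had a median of -0.06 (0.271), with the lymph node homing receptor gene Ccr7 at 7.43 ± 0.56 in sham and 6.42 ± 0.52 in irradiated mice (SD, n = 4 each). Alternative activation and immune suppression genes had a median of 0.01 (0.169), with Retnla at 0.76 ± 0.38 (SE), or 0.35 without irradiated mouse 3. Medians lay within 0.07 of 0 for the lists of the NRF2 antioxidant response (adjusted p = 0.739), the unfolded protein and integrated stress response (0.301), apoptosis (0.861) and ribosomal proteins (0.317). For lysosome and autophagy (median 0.01, mean -0.00, adjusted p = 0.339) and for hypoxia and glycolysis (median 0.00, mean -0.02, 0.805), camera's direction was higher while the mean was below 0. Among markers of other cells, medians were -0.09 for dendritic cells (0.306), 0.06 for fibroblasts and pericytes (0.162), 0.00 for endothelium (0.301) and -0.07 for erythroid cells and platelets (0.867). Epithelial and tumour cell markers (median -0.01, mean 0.03, adjusted p = 0.306) and those of eosinophils, basophils and mast cells (median -0.00, mean -0.02, 0.533) also differed in sign between these measures, camera's direction being higher for both. Without single arrays, 4 more of these lists passed. Fibroblast markers passed as higher without sham mouse 3 (adjusted p = 0.000172) or irradiated mouse 2 (0.0475) or 3 (0.00173). Epithelial markers passed as higher without sham mouse 3 (0.00124) or irradiated mouse 2 (0.0305). Alternative activation genes passed as higher without sham mouse 4 (0.0140) or irradiated mouse 1 (0.0271). The receptors passed as lower without sham mouse 3 (0.0271).

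**Figure D3:**
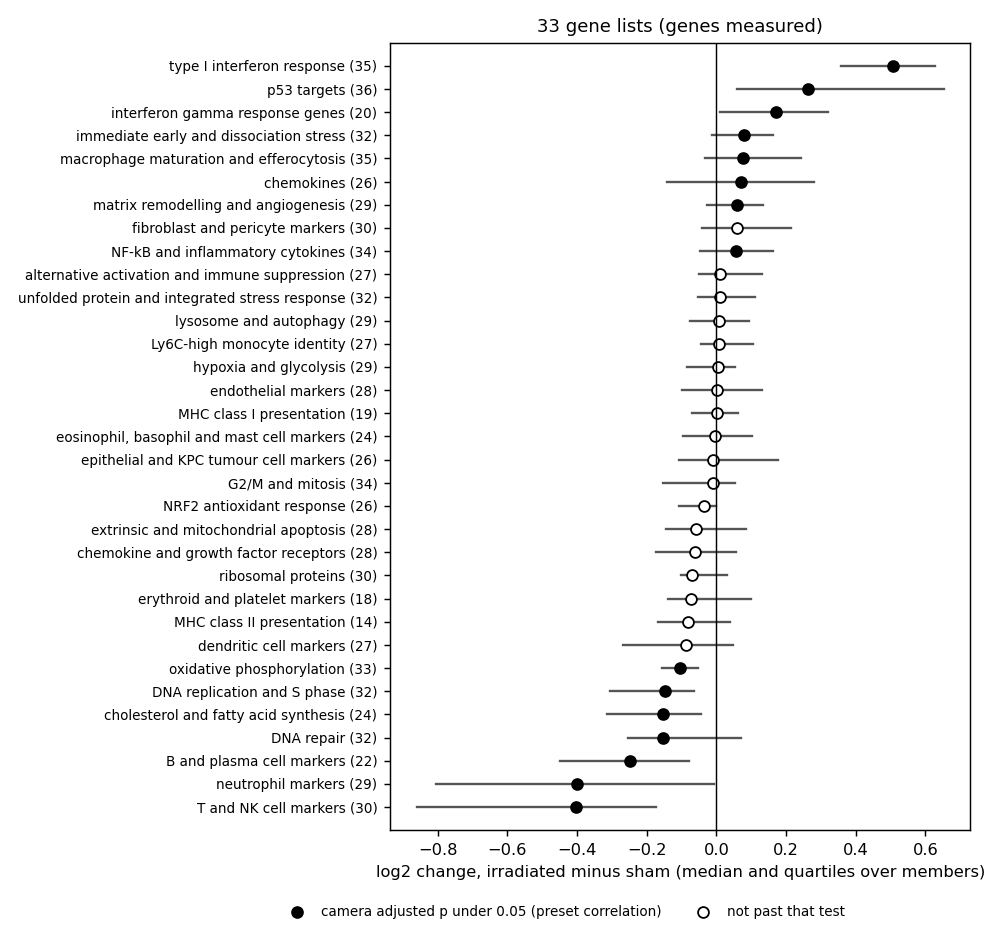
Log2 change, irradiated minus sham (x axis, 4 mice per group), for 33 gene lists, with the number of genes measured in brackets; points show the median over a list's genes and lines its quartiles. Filled points mark the 15 lists past an adjusted p of 0.05 in camera with its preset correlation, 8 higher and 7 lower.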

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

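The tests in this part were chosen after the result was seen, except the counts over other splits of the arrays for genes at an unadjusted p and for called lists. The real split gave 0 genes past the adjusted threshold in limma (1347 at an unadjusted p under 0.05), so each of the 35 of 35 ways to split the 8 arrays into 4 and 4 gave at least as many by construction, and this count tests nothing; the highest other split gave 144. For genes at an unadjusted p under 0.05, 6 of the 35 splits gave 1347 or more (highest other 2419), and 10 of 35 called 15 or more lists (highest other 21), so chance was not excluded for either count. The split that gave 144 genes set sham mice 1 and 4 and irradiated mice 2 and 3 against the rest, and points to a structure of the samples that cuts across the treatment.

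The p53 targets were 0.33 higher on the log2 scale after irradiation, and 1 of the 35 splits, the real one, gave a difference as large (highest other 0.30), the smallest share that 35 splits allow. The exact permutation p was 0.471 after adjustment over the 33 lists. With only 2 lists at the smallest p that the 70 assignments allow, no list could pass this adjustment. The adjusted p therefore does not decide whether chance gave the difference, and chance was not excluded. With 1 mouse left out, the unadjusted exact permutation p was 0.0857 for each sham mouse and 0.0286, the smallest possible, for each irradiated mouse. The groups stayed apart each time. The difference was 0.31 to 0.35 with a sham mouse left out and 0.23 to 0.40 with an irradiated mouse left out. The p of 0.0857 arose because, with groups of unequal size, some other assignments gave as large an absolute difference. Carried-over lymphocytes and tumour cells, the latter without CD45 and so outside the gate, were weighed by adding their marker list means as covariates: the difference was 0.27 ± 0.11 (SE) with the T and NK list and 0.34 ± 0.12 with the epithelial list, and array scaling by subtracting each array's median, which left 0.34 ± 0.12. All 3 estimates stayed positive, although each rests on 8 arrays. Neither the epithelial list nor array scaling reduced the difference. With the T and NK list it was smaller and not large against its SE for 8 arrays. The covariate fit alone therefore does not exclude carried-over lymphocytes. Sham mice 1 and 4 and irradiated mice 2 and 3 had close T and NK list means, at 5.54, 5.83, 5.57 and 5.47. Their p53 list means were 7.19, 7.11, 7.52 and 7.74. On these arrays the values argue against T and NK cells as the source of the whole difference. Carried-over cells were not excluded as a source of a part of the difference. A response of the sorted cells to their own irradiation, and the arrival of different cells in irradiated tumours, may each underlie it and stay open, since no measurement here separates them.

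The type I interferon list stood highest in irradiated mice 1 and 2, and 6 of the 35 splits gave a difference as large as the real 0.52 (highest other 0.59), so chance was not excluded. Array scaling does not account for it: on the array of irradiated mouse 1 the ribosomal protein list exceeded the other irradiated arrays by 10.8% of the interferon list's excess of 0.84. Carried-over T and NK cells would raise their own markers by at least as much, but the median excess of irradiated mice 1 and 2 over mice 3 and 4 was 0.0465 (SD 0.343) over the 30 T and NK cell genes, against 0.86 (SD 0.39) over the 35 interferon genes. Over the 27 dendritic cell genes the median excess was -0.0274 (SD 0.362). These genes hardly varied together (camera's estimated correlation 0.04), so their median may not follow the share of these cells. Dendritic cells were therefore not excluded. What set irradiated mice 1 and 2 apart stays open.

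T and NK cell markers spanned 1.94 on the log2 scale over the 8 arrays, a 3.84-fold range. Cells of other types in the sort are a candidate source. For the 30 genes, within-group deviations had a median pairwise correlation of 0.74. The 99th percentile of 1000 random lists of matched level was 0.098. The list was picked for its uneven mean, which requires members that vary together. The comparison therefore does not tell carried cells from another shared source. Camera's estimated correlation was 0.61 for this list and 0.68 for the type I interferon list. Of genes named after their values were seen, Cd3g stood at 9.53 and 9.66 in sham mice 2 and 3 against 5.53 and 6.36 in sham mice 1 and 4, and Nkg7 at 9.76 and 9.52 against 6.45 and 6.78. Array scaling does not account for it, since the ribosomal protein list's range was 9.97% of this list's. A strict CD11b-positive, Ly6C-high gate would remove most T cells, but some activated T and NK cells carry both antigens; 1 of the 30 genes is also on another list.

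Within groups of 4, 16 of 248 sets of values had 1 mouse set apart from the other 3; chance flags about 1 in 20 groups, or 12.4 here. Among list means, G2/M and mitosis stood at 6.29 in sham mouse 3 (others 5.59 to 5.70), matrix remodelling at 8.26 in sham mouse 4 (7.97 to 8.00) and oxidative phosphorylation at 9.71 in irradiated mouse 1 (9.50 to 9.53). DNA replication stood at 5.91 in irradiated mouse 2 (6.17 to 6.22) and endothelial markers at 4.66 in irradiated mouse 3 (4.87 to 4.89). Among genes in sham mice, H2ac15 stood at 8.44 and Cdk1 at 7.65 in mouse 4, Bank1 at 7.09 and Itgb4 at 5.51 in mouse 3, and Uqcrc2 at 9.37 in mouse 2. In irradiated mice, mouse 3 stood apart for Mmp2 at 7.69, Ccr2 at 11.2, Nlrc5 at 6.65 and St14 at 5.24, mouse 1 for Mcm10 at 5.00, and mouse 4 for Ctsz at 10.7.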

How the results depend on the processing

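The settings with the T and NK list mean as a covariate and without sham mice 2 and 3 were chosen after the data were seen; the rest were fixed before. The count of 0 genes held under every setting but 1: leaving out each array gave 0 to 1 genes changed and 0 to 1 lower. With dim genes left out, 805 genes had an unadjusted p under 0.05, since fewer genes were tested. Of 1540 named-gene values, 1536 kept their direction and side of the threshold. This count says little, since no gene passed and most named genes were picked for a small p in these data.

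With the correlation estimated, 0 lists passed, and by fry 0. The adjusted p of p53 targets was then 0.622 and 0.372, and that of type I interferon genes 0.622 and 0.682; with the preset correlation both passed throughout, p53 targets at 2.13e-14 to 1.99e-08. Fry for change in either direction gave an adjusted p of 0.0407 for p53 targets and for cholesterol and fatty acid synthesis. For type I interferon genes it gave 0.837. With camera at the preset correlation, leaving out each array gave 7 to 16 lists. Of the 15 calls, 13 were lost without at least 1 array.

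Among lists past the threshold in the report or under the alternative, and among named genes, directions reversed as follows, and the cause was not tested. With the T and NK covariate, the adjusted p was 0.00384 for G2/M, 0.725 for macrophage maturation and 0.0429 for hypoxia. Without sham mice 2 and 3, Camp was 0.15 and the adjusted p was 0.00723 for G2/M, 0.455 for NF-kB, 0.679 for chemokines, 0.475 for macrophage maturation, 0.023 for hypoxia, 0.996 for immediate early genes, 0.000346 for T and NK and 0.416 for B cell markers. These 2 settings called 14 and 12 lists, 6 of the original 15 in each, though T and NK markers in the second setting passed in the opposite direction. Lists that passed under these settings but not in the report were, with the covariate, fibroblast (6.02e-08), epithelial (0.000822) and endothelial markers (0.00617) and Ly6C-high monocyte identity (0.0285) as higher and receptors (0.00176) and NRF2 (0.0429) as lower, besides G2/M and hypoxia. Without sham mice 2 and 3 they were fibroblast (5.92e-06), epithelial (5.59e-05) and endothelial markers (0.00258) as higher and receptors (0.00567) as lower, besides G2/M and hypoxia. Calls also lost there were DNA repair (0.0924), oxidative phosphorylation (0.387), matrix remodelling (0.185) and neutrophil markers (0.253). With single arrays left out, G2/M ranged from 0.00425 to 0.781, Ly6c2 from -0.0204 to 0.539 and Ptprc from -0.0636 to 0.00654. Of 342 values of the 18 lists that did not pass in the report, 41 had the opposite direction, most of them past the threshold in neither setting.

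Mouse numbers did not pair the arrays: deviations of same-numbered mice correlated at -0.28, -0.17, -0.18 and -0.14, and none correlated best with its own number. With the number as a block, 0 genes passed, 1065 had an unadjusted p under 0.05 and 12 lists passed. Signal over background was not tested, as no detection calls were used.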

Other observations

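The hypothesis and its test in this part were chosen after the result was seen. The largest axis of difference among the arrays ran within the groups: the first principal component held 42.8% of the variance, of which treatment accounted for 4.63%. Its scores were 15.5 and 26.8 for sham mice 2 and 3 and 11 and 8.17 for irradiated mice 1 and 4, against -14.7 and -13.6 for sham mice 1 and 4 and -14.7 and -18.4 for irradiated mice 2 and 3. The lists and genes of this paragraph were chosen after their values were seen. On the 4 arrays with positive scores, sham mice 2 and 3 and irradiated mice 1 and 4, the T and NK cell list stood at 7.24, 7.41, 6.44 and 6.48 and the fibroblast and pericyte list at 6.00, 6.57, 6.39 and 6.33. On sham mice 1 and 4 and irradiated mice 2 and 3 they stood at 5.54, 5.83, 5.57 and 5.47 and at 5.37, 5.84, 5.76 and 5.50. Lists of macrophage functions ran the other way: lysosome and autophagy genes stood at 9.15, 9.01, 9.03 and 9.09 on the first 4 arrays and at 9.32, 9.38, 9.28 and 9.46 on the others. Alternative activation genes stood at 8.46, 8.20, 8.31 and 8.57 against 8.66, 8.78, 8.63 and 8.74. Of the 8 lists called higher after irradiation, 4 leaned most clearly the same way as these. Macrophage maturation genes stood at 8.79 to 9.19 against 9.24 to 9.59, and immediate early genes at 9.56, 9.56, 9.51 and 9.83 against 9.83, 9.83, 9.85 and 9.91. NF-kB genes (8.56, 8.38, 8.60 and 8.74 against 8.70, 8.98, 8.84 and 8.77) and chemokine genes (9.48, 9.17, 9.54 and 9.41 against 9.49, 9.94, 9.72 and 9.73) did so with some overlap. The p53 list (7.13, 7.06, 7.25 and 7.30 against 7.19, 7.11, 7.52 and 7.74) and the matrix remodelling list (7.97, 8.00, 8.11 and 8.07 against 7.98, 8.26, 8.13 and 8.29) overlapped too. The type I interferon list did not follow the scores (8.24, 8.06, 9.42 and 8.38 against 8.32, 8.46, 9.06 and 8.31), nor did the interferon gamma list (8.25, 8.19, 8.50 and 8.32 against 7.96, 8.40, 8.35 and 8.31). The neutrophil list did not follow the scores, at 6.85, 7.66, 6.26 and 6.12 against 7.16, 7.01, 6.82 and 7.47, although its member Cxcr2 stood at 6.95, 7.40, 6.32 and 6.69 against 9.72, 9.35, 9.05 and 10.04. The granule gene Ngp, made by neutrophil precursors, stood at 7.78 and 10.1 in sham mice 2 and 3 and at 3.93 to 4.79 on the other 6 arrays.

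One hypothesis was that arrays with fewer freshly recruited monocytes show more of the p53 targets. The within-group deviations of the p53 and Ly6C-high monocyte identity lists correlated at r = -0.78 over 8 arrays (exact permutation p = 0.102, adjusted 0.307; Spearman rho = -0.52, exact p = 0.319, adjusted 0.661; 3 relations in the family, the other 2 being the interferon list with the T and NK and the dendritic cell lists, each at an adjusted permutation p of 0.891). Without the 2 arrays farthest from the median r was 0.04, so the relation rests on those arrays. The test leaves the hypothesis undecided.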
